A study of Arabidopsis thaliana with 9 samples.

How the data were processed

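Transcript levels were measured on Affymetrix ATH1 arrays, 1 array per sample, in inflorescences of 3 groups with 3 biological replicates each: DEX at 0 h, DEX at 4 h and MOCK at 4 h. The deposited values are probe set intensities on a linear scale, made by the authors with the Microarray Suite (MAS 5.0), per the labels' design text. In the deposited intensities the 2% trimmed mean is 500.04 on each array, so the arrays were taken as already scaled to a common level; the step itself is not given in the sources used here. Image files and the detection and change calls were not used here. Groups were taken from the sample labels, and 0 columns were left out.

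The values were transformed to log2(signal + 16), so fold changes of weak signals are understated. The 64 control probe sets and the 30% of the remainder with the lowest mean (6824 probe sets) were left out, leaving 15922 for testing. One linear model with a mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), so that the groups share an estimate of the spread. The contrasts were DEX 4 h against MOCK 4 h, DEX 4 h against DEX 0 h and MOCK 4 h against DEX 0 h, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values for genes are from limma. Errors given as SE are from that fit, and means and SDs are of the linear signal over 3 arrays. Tested on simulated data with 200 changed among 15922 probe sets, the fit recovered 38.8% of log2 changes of 1, 90.8% of changes of 2 and 98.4% of changes of 3 for DEX 4 h against MOCK 4 h. The simulated arrays varied independently, without pairing, batches or an outlying array. These shares therefore do not show that changes of such sizes are absent where few or no probe sets passed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

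Genes were named from the platform's annotation, updated through a table of RefSeq locus tags. Of 22810 probe sets, 13513 were paired with 1 gene, 503 with several and 8730 are unnamed here; 13436 matched a RefSeq locus. Of the 366 genes on 23 lists fixed before the data were examined, 55 have a named probe set and 46 were tested, which limits what the lists can show. Lists with at least 3 tested members were tested with camera (preset correlation 0.01), adjusted over 9 lists per comparison, and again with an estimated correlation and with fry. The list of plastid-encoded genes was added later and adjusted with the 9 others.

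The rule for named genes was fixed before the data were examined. Per comparison it takes up to 12 rising and 12 falling probe sets past the threshold that map to 1 gene, do not overlap between the groups and exceed the median signal in the higher group. It adds up to 4 members past the threshold per list, the fixed set of AP3/PI-related genes whatever their values, up to 12 rising and 12 falling genes changed only after DEX, and, where fewer than 10 probe sets pass, the 12 with the smallest p whose groups do not overlap. List members given as examples and the genes under the other observations were added after their values were seen.

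Whether the replicate numbers pair the arrays was checked by correlating deviations from the group means. Arrays of equal number correlated at 0.413, 0.532 and 0.565 between DEX 0 h and DEX 4 h, above the limit of 0.1 in every pair, so the numbers pair those 2 groups in the data, though the labels do not state a shared batch. The fit of all 9 arrays does not use the pairing, and a paired fit of 2 groups was run as an alternative. Technical batches were read from the arrays after seeing the data, from the 5' to 3' ratios of the control transcripts and the spread of the signals. One holds the 3 arrays numbered replicate 3, another DEX 0 h and DEX 4 h replicate 1 with MOCK replicate 2, and another DEX 0 h and DEX 4 h replicate 2 with MOCK replicate 1. Each batch so read holds 1 array of each group. Deviations within the assigned batches correlated at 0.143 and 0.318 between DEX 0 h and the MOCK array of unlike number and at -0.0013 and 0.405 between DEX 4 h and that array, so the deviations do not bear out placing MOCK replicate 2 with DEX 4 h replicate 1, and values by batch carry that limit. Alternatives covered the log2 offset, the dim filter, quantile normalization and median centring, the variance model, array weights, the arrays in the fit, replicate and technical blocks, the threshold, a fold rule and leaving out each array in turn.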

Results

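The measurements are transcript levels in inflorescences of Arabidopsis thaliana plants that carry a dexamethasone-inducible form of APETALA3 (AP3). AP3 and PISTILLATA (PI) are MADS-box transcription factors that act together to specify petals and stamens. In these plants a 35S promoter drives AP3 fused to the glucocorticoid receptor domain (AP3-GR), which keeps a protein out of the nucleus until the steroid dexamethasone (DEX) is given. PI is also driven by 35S, and the plants lack their own functional AP3 because of the ap3-3 allele. The stated purpose was to find genes that respond only to DEX, as candidate targets of AP3/PI. The 9 arrays form 3 groups of 3 biological replicates: DEX at 0 h, DEX at 4 h and a MOCK treatment at 4 h. Each array gave a signal for 22810 probe sets, and the median signal per array lay between 202 and 236. With 3 arrays per group, the number of arrays limits the precision. The 5' to 3' signal ratio of the actin control, a measure of RNA integrity and labelling, was 0.158 to 0.233 on the 3 arrays numbered replicate 3 and 0.437 to 0.671 on the other 6 arrays. The probe sets of AP3, PI and most floral regulators are unnamed in the annotation used here, so the transgene and the mutated gene were not checked by their own signal. RABBIT EARS (RBE), a petal regulator and the only gene of the fixed set of AP3/PI targets with a named probe set, differed by a log2 value of -0.36 (SE 0.351, adjusted p = 0.809 by limma) between DEX and MOCK at 4 h. Its signal was weak, at 47.9 ± 18.3 (SD, n = 3) after DEX, 64.7 ± 11.2 after MOCK and 48.9 ± 20.7 at 0 h. These means lie near the limit of about 51.4 under which probe sets were not tested, so a response of RBE may have been missed.

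The comparison of DEX with MOCK at 4 h asks what DEX changed at a matched time. No transcript passed the threshold, but JMT, which encodes jasmonic acid carboxyl methyltransferase, the enzyme that makes methyl jasmonate, had the smallest p. Its signal was 557 ± 174 (SD, n = 3) after DEX, 54.65 ± 10.02 after MOCK and 173 ± 89.1 at 0 h. Every DEX array lay above every MOCK array, which the naming rule required of the transcripts taken here. The log2 difference was 2.99 (SE 0.375), with an adjusted p of 0.149 by limma. The 4-coumarate:CoA ligase-like gene 4CL8 had 379 ± 29.3 after DEX against 135 ± 20.98 after MOCK and 134 ± 39.5 at 0 h, a log2 difference of 1.39 (SE 0.237, adjusted p = 0.160). AT3G44450, which encodes BIC2, an inhibitor of the blue-light receptors called cryptochromes, stood at 305 ± 109 after DEX and 57.7 ± 24.7 after MOCK, but its signal at 0 h was already 274 ± 62.7. Of the 7 probe sets without a single named gene that the naming rule took here, the MOCK mean was the lowest of the 3 group means in 6, with log2 differences from 0.92 to 2.86, and the highest in 1, at -1.27. AT5G62280 was lower after DEX, at 94.3 ± 15.74 against 285 ± 42.3, with a 0 h value of 183 ± 25.3 and a log2 difference of -1.45 (SE 0.214, adjusted p = 0.158). AT3G05190 differed by 1.13 (SE 0.178, adjusted p = 0.158).

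**Figure D1:**
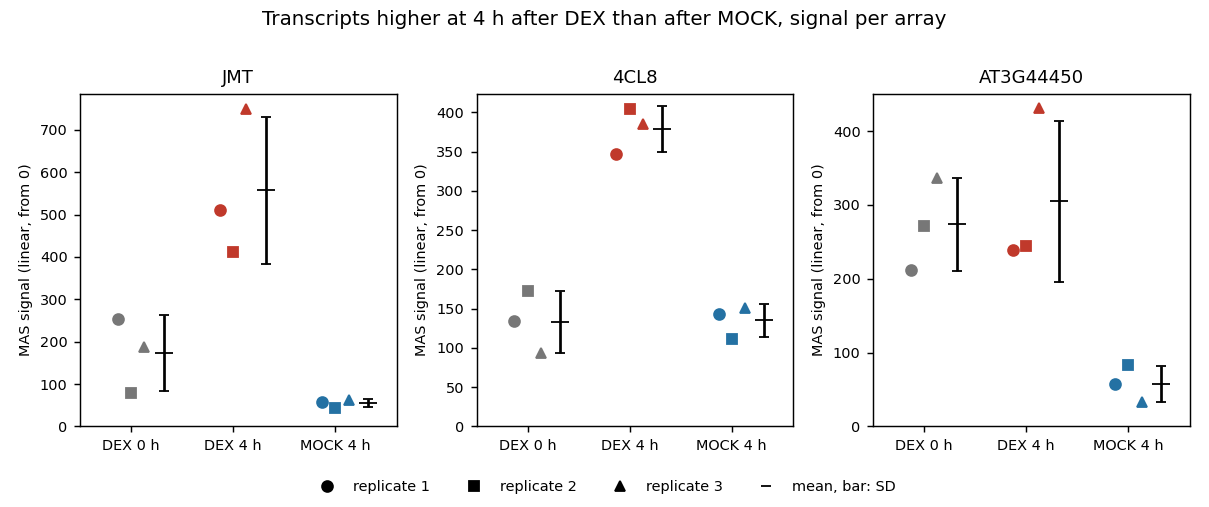
Signal on the linear scale (y axis) of JMT, 4CL8 and AT3G44450 on each of the 9 arrays, by group (x axis). Symbols give the replicate number, and the bars give the mean and SD of 3 arrays. JMT and 4CL8 were highest at 4 h after DEX, whereas AT3G44450 had similar signals at 0 h (274) and 4 h after DEX (305) and a signal of 57.7 after MOCK.

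Of 15922 probe sets tested between DEX and MOCK at 4 h with limma, 0 rose and 0 fell at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 1558 (9.79%), where 796 are expected by chance, and in 1982 (12.4%) the arrays of the groups did not overlap, where chance gives 10%. Without MOCK replicate 2 there were 371 (156 higher and 215 lower after DEX), and without DEX 0 h replicate 2 there was 1. Weighting the arrays gave 35, a fit of only these 2 groups gave 1 (JMT, adjusted p = 0.0392), and a block for technical batches read from the arrays, chosen after seeing the data, gave 19. Over all alternatives the adjusted p of JMT ran from 0.0137 without DEX 0 h replicate 2 to 0.716 without MOCK replicate 1, and it was 0.0191 without MOCK replicate 2. That of 4CL8 was under 0.05 with array weights (0.0404) and without MOCK replicate 2 (0.0391), and reached 0.716 without MOCK replicate 1. These p-values rest on the spread between arrays of biological replicates, 3 per group. In fits without a block that spread also holds any differences between technical batches.

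**Figure D2:**
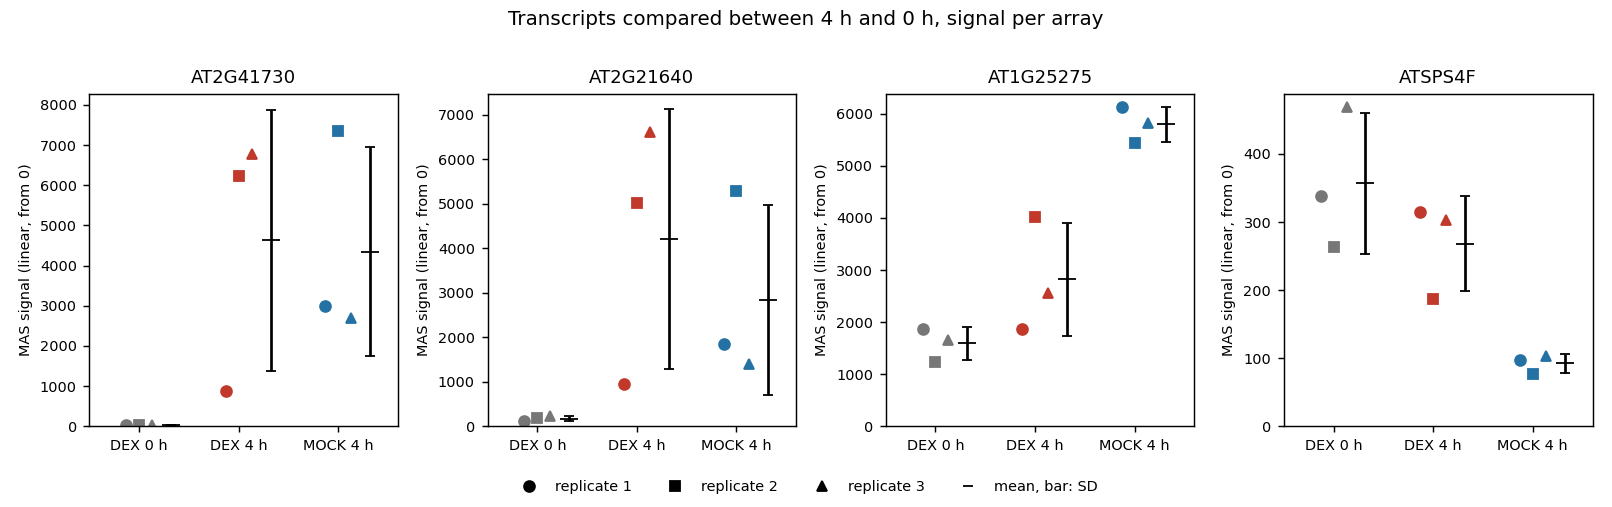
Signal on the linear scale (y axis) of AT2G41730, AT2G21640, AT1G25275 and ATSPS4F on each of the 9 arrays, by group (x axis). Symbols give the replicate number, and the bars give the mean and SD of 3 arrays. AT2G41730 was at 27.2 on average at 0 h and at 4632 and 4351 at 4 h after DEX and MOCK, and DEX replicate 1 had the lowest of the 4 h signals.

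The comparison of DEX at 4 h with DEX at 0 h asks what changed over 4 h of treatment. AT2G41730, a gene that responds to oxidative and low-oxygen stress, rose from 27.2 ± 3.68 (SD, n = 3) at 0 h to 4632 ± 3252 at 4 h, a log2 change of 6.29 (SE 0.668, adjusted p = 0.0319 by limma). Its probe set is of a type that can share signal with related transcripts. It was also at 4351 ± 2605 after MOCK, a log2 difference from 0 h of 6.51. Among the transcripts with the next smallest p, none past the threshold without pairing, were AT2G21640, a marker of oxidative stress, at 172 ± 53.7 and 4204 ± 2923 (log2 4.13, SE 0.678, adjusted p = 0.223), and AT5G40690 at 73.3 ± 13.5 and 928 ± 709.5 (log2 3.06, SE 0.560, adjusted p = 0.314). The 7 probe sets without a single named gene that the rule took were all higher at 4 h, by log2 values of 3.36 to 5.51. The signals of these transcripts were spread widely among the DEX arrays at 4 h. 4CL8 differed by 1.43 (SE 0.237, adjusted p = 0.223) and AT4G00920 by -1.21 (SE 0.214, adjusted p = 0.284). In all, 1 probe set rose and 0 fell, 747 (4.69%) had an unadjusted p under 0.05 without pairing (2179 in the paired fit of these 2 groups), where 796 are expected, and 1467 (9.21%) did not overlap, where chance gives 10%. The replicate numbers pair these 2 groups, and with only their arrays in that paired fit and the number as a block, chosen after seeing the data, 6 rose and 0 fell, among them AT2G41730 and AT2G21640 (adjusted p = 0.0482 each). A block over all 9 arrays, where the MOCK numbers do not pair, gave 0 and an adjusted p of 0.0568 for AT2G41730, which ran from 7.7e-05 to 0.395 over all alternatives. Without DEX replicate 1 at 4 h, 76 passed (75 rose and 1 fell), and leaving out any other single array except MOCK replicate 2 gave 0.

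The comparison of MOCK at 4 h with DEX at 0 h asks what differed after 4 h without DEX. There are no MOCK arrays at 0 h, so time, the MOCK treatment and any difference between the plants cannot be told apart. With all arrays this comparison held the most calls. Without MOCK replicate 2 it had 289 and DEX against MOCK had 371, and without DEX 0 h replicate 2 they had 0 and 1. Of 15922 probe sets, 21 rose and 37 fell with limma at an adjusted p of 0.05, and the 22 of these taken by the naming rule had adjusted p from 0.0142 to 0.0499. Besides AT2G41730, the rising named transcripts were AT3G04010, a glycosyl hydrolase (log2 4.29, SE 0.617), AT4G28140, an AP2/ERF transcription factor (3.71, SE 0.586), AT5G40690 (3.36), the dehydrin AT4G38410 (3.20), AT3G59350 (2.14), AT1G05340 (2.08), AT1G25275 (1.87), the desiccation-responsive RD2 (1.35) and AT3G51450 (1.31). AT1G25275 went from 1593 ± 323 to 5800 ± 340 (SD, n = 3) and RD2 from 1687 ± 378 to 4277 ± 250. The falling named transcripts included AT2G19650 (log2 -2.93), AT1G13650 (-2.75, SE 0.384), the cryptochrome inhibitor gene AT3G44450 (-2.01, SE 0.322), AT3G01060 (-1.81, SE 0.255) and ATSPS4F, a sucrose phosphate synthase (-1.75, SE 0.269). The others were AT5G21100, an ascorbate oxidase (-1.60), AT1G07450 (-1.60), AT2G04039 (-1.55), AT5G64850 (-1.47), AT5G62140 (-1.28), AT4G16140 (-1.22) and AT3G56370 (-0.91). ATSPS4F went from 357 ± 104 to 92.8 ± 13.9, and AT3G01060 from 1104 ± 240 to 299 ± 17.59. At an unadjusted p under 0.05 there were 2064 probe sets (13.0%), and 2613 (16.4%) did not overlap, where chance gives 10%. The count fell to 3 with no filter on dim probe sets and to 3 without the intensity trend, and rose to 587 with array weights and to 396 with the technical block. It was 289 without MOCK replicate 2, 212 without DEX 4 h replicate 1, 155 without DEX 4 h replicate 2, 37 without DEX 4 h replicate 3, 1 without DEX 0 h replicate 1, and 0 without any one of DEX 0 h replicates 2 and 3 and MOCK replicates 1 and 3. Over all alternatives the adjusted p of AT2G41730 ran from 7.4e-05 to 0.0971. Within technical batches, the MOCK array had the lowest 5' to 3' ratio in 6 of 9 comparisons of the actin, GAPDH and ubiquitin controls, all 6 on MOCK replicates 1 and 3. The batches were read partly from these same ratios.

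**Figure D3:**
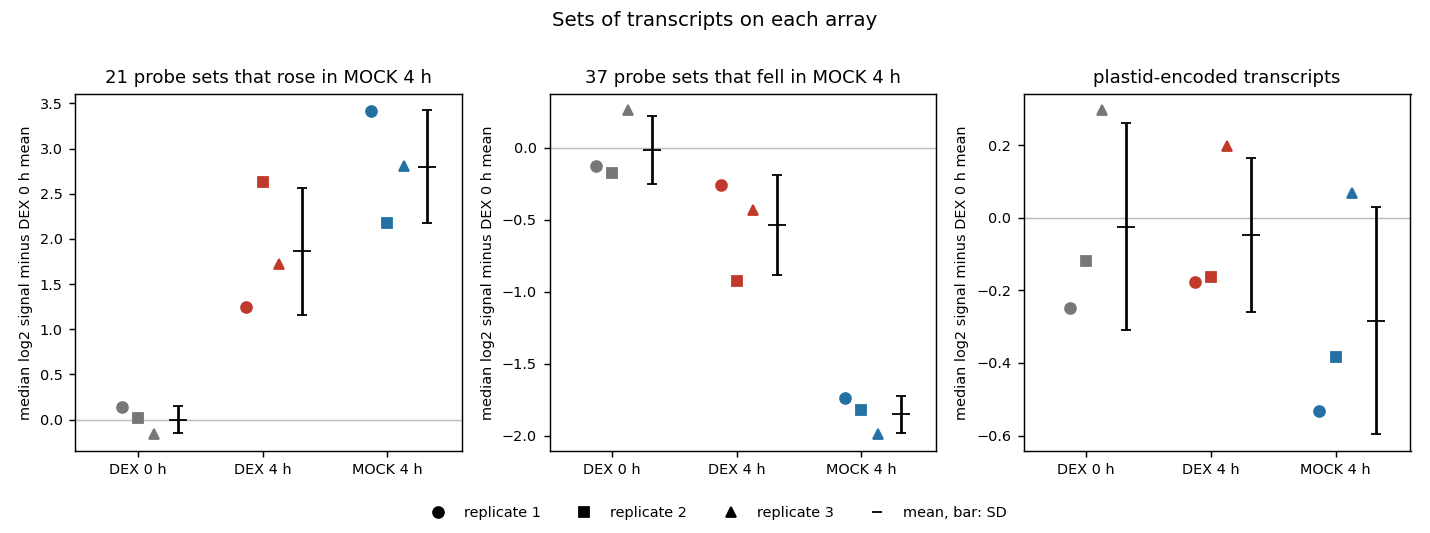
Median log2 signal relative to the mean of the DEX 0 h arrays (y axis) on each array, by group (x axis), for the 21 probe sets that rose and the 37 that fell in MOCK at 4 h against 0 h, and for the 69 probe sets of plastid-encoded transcripts. Symbols give the replicate number, and the bars give the mean and SD of 3 arrays; the first 2 sets were chosen for their MOCK values, and the falling set lay between -0.26 and -0.93 on the DEX 4 h arrays against -1.74 to -1.99 on the MOCK arrays.

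The probe sets that changed in MOCK were followed in the DEX arrays at 4 h. Of the 21 that rose in MOCK, 21 were higher at 4 h after DEX than at 0 h, and of the 37 that fell, 35 were lower. The sets were chosen on the same 0 h arrays, so 50 simulations without any effect, in which genes vary independently, chose sets of these sizes likewise. With independent arrays they shared the sign in 19.7 of 21 and 34.2 of 37 in the mean, with highest values of 21 and 37. With DEX 0 h and DEX 4 h arrays paired at the mean correlation of 0.503 the means were 17.7 and 30.7 and the highest values 20 and 35, so the 35 observed was reached in both kinds of simulation and the 21 only with independent arrays. The median log2 difference of the rising set at 4 h after DEX was 1.89 (3.04 in MOCK), where the simulations reached 0.84 with independent and 0.47 with paired arrays. That of the falling set was -0.60 (-1.78 in MOCK), where they reached -0.68 and -0.36, so it lies within the values of independent arrays and beyond those of paired ones. The sizes in MOCK are inflated by the choice of the sets. Groups with a change in MOCK but none after DEX were not simulated, so these values are set only against groups without any change. Across all tested genes, which are not independent replicates, the differences from DEX at 0 h after DEX and after MOCK correlated at r = 0.614. Simulated groups with no effect that share the 0 h arrays gave a mean of 0.503 with independent and 0.354 with paired arrays. The covariance was 0.123 against a simulated 0.0468 and 0.0231, differences of 0.0765 and 0.1002. One transcript, AT2G41730, was called in both, where independent lists would share 0.0036, and part of that excess can come from the shared arrays, which were too few to split. For DEX against MOCK and DEX against 0 h, which share the DEX 4 h arrays, r was 0.155 against a simulated 0.497 with independent and 0.350 with paired arrays, and the covariance was 0.0249 against 0.0461 and 0.0228.

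Genes changed only after DEX were defined as passing the threshold against both MOCK at 4 h and DEX at 0 h, in one direction, and not in MOCK against 0 h. With limma 0 probe sets met this definition, and 104 (46 higher and 58 lower) met it at an unadjusted p of 0.05 in each test. The 2 tests share the DEX 4 h arrays, and the count expected without any effect was not computed. The 104 therefore cannot be read as more than chance gives. A fold rule that asks for at least 1.5-fold in the same direction in all 9 array-by-array comparisons, and for this not to hold in MOCK against 0 h, gave 2, both higher after DEX. They were 4CL8 and JMT, named here after their values were seen. 4CL8 differed between MOCK and 0 h by a log2 value of 0.04, whereas JMT was lower in MOCK (54.65) than at 0 h (173). Between DEX at 4 h and 0 h, JMT differed by a log2 value of 1.69 (adjusted p = 0.477 by limma).

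Of 23 gene lists fixed in advance, 9 had at least 3 tested members, and no member of any list passed the threshold over all genes in any comparison. Against MOCK at 4 h, the gibberellin list was lower as a set after DEX (median log2 -0.53, camera adjusted p = 0.0232; adjusted p = 0.220 with an estimated correlation). Its tested members, 3 of 19 on the list, were the gibberellin receptor genes GID1A (-0.87), GID1B (-0.35) and GID1C (-0.53). All 3 were lower, and 1 passed when adjusted over the list alone. The phenylpropanoid and flavonoid list was higher as a set (median 0.96, adjusted p = 0.0302; adjusted p = 0.272 with an estimated correlation). Its 3 tested members, of 20 on the list, were the flavonoid glucosyltransferase UGT78D2 (1.23), the dihydroflavonol reductase DFR (0.96) and the flavonol rhamnosyltransferase UGT78D1 (0.81). Of these, 0 passed when adjusted over the list alone. Within the 3 technical batches, of which the one with MOCK replicate 2 is borne out only in part by the replicate deviations, the median was -0.60, -0.54 and -0.63 for gibberellin and 1.3, 0.83 and 0.75 for flavonoids. Without MOCK replicate 1 or MOCK replicate 2 neither list passed, at adjusted p of 0.0805 and 0.0654 for gibberellin and 0.101 and 0.0654 for flavonoids, and without DEX 4 h replicate 1 the flavonoid list had 0.123. The gibberellin median was then -0.31 without MOCK replicate 1 and -0.77 without MOCK replicate 2, and the flavonoid median 0.93, 1.19 and, without DEX 4 h replicate 1, 0.55. The cold and water deficit list (median -1.22, adjusted p = 0.0914) passed without DEX 0 h replicate 1 (0.0225) or DEX 0 h replicate 3 (0.0237). Against 0 h, with all arrays, the gibberellin median was 0.11 after DEX and 0.63 in MOCK. The flavonoid median was -0.18 after DEX and -0.99 in MOCK. For these lists the difference between DEX and MOCK thus lay mostly on the MOCK arrays, which the comparison of MOCK with 0 h shares.

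In MOCK at 4 h against 0 h, 3 lists passed with the preset correlation. In MOCK the cold and water deficit list was higher (median 1.89, camera adjusted p = 0.0244), but the adjusted p was 0.310 with an estimated correlation. Its tested members, 3 of 12 on the list, were COR47 at 1.45, COR15A at 1.89 and COR15B at 2.39, genes of cold acclimation. All 3 passed when adjusted over the list alone. The gibberellin list was higher (median 0.63, adjusted p = 0.0244, 1 adjusted over the list alone) and the phenylpropanoid and flavonoid list was lower (median -0.99, adjusted p = 0.0244, 2 adjusted over the list alone). With an estimated correlation the adjusted p was 0.294 for each of these 2 lists. The cold list varied among the 0 h arrays, where COR15B read 4420, 1316 and 181, and within technical batches its median was -0.08, 2.08 and 4.11. The gibberellin medians within batches were 0.40, 0.85 and 0.26 and the flavonoid medians -0.95, -0.98 and -1.04. Without DEX 0 h replicate 3 none of the 3 lists passed (adjusted p = 0.0577, 0.0522 and 0.0577), and without DEX 0 h replicate 1 or MOCK replicate 1 the gibberellin and flavonoid lists did not pass (0.0501 and 0.0944 for the first array, 0.0635 for both lists for the second). The cold median was 1.06 without DEX 0 h replicate 3 and 2.90 without DEX 0 h replicate 1, and without MOCK replicate 1 the gibberellin median was 0.41 and the flavonoid median -0.74. In DEX at 4 h against 0 h, 0 lists passed. Without DEX 0 h replicate 1 the cold list did, at a median of 1.57 and an adjusted p of 0.00132.

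The other lists with at least 3 tested members did not pass in any comparison with all arrays. Light harvesting and Rubisco in MOCK against 0 h (median -0.59, adjusted p = 0.0721) passed without DEX 0 h replicate 2 (0.0302) or MOCK replicate 3 (0.0449), and heat shock passed with no dim filter in both comparisons with 0 h (0.0297 for DEX and 0.0293 for MOCK). Between DEX and MOCK at 4 h, the petal list had a median log2 difference of 0.05 over 5 members, the gynoecium and ovule list -0.06 over 7, chlorophyll biosynthesis -0.45 over 3 and light harvesting and Rubisco 0.34 over 4. The heat shock list stood at 0.06 over 3 members and the cell cycle list at 0.25 over 3, where the replication gene MCM7 had 1.00 (adjusted p = 0.325). The signs of the heat shock median and its camera direction differed there, as did those of gibberellin for DEX at 4 h against 0 h and of chlorophyll biosynthesis for MOCK against 0 h. Lists with 1 or 2 tested members had no set test. Their values between DEX and MOCK were 0.05 for AGL24 (floral identity), 0.18 for EMS1 and -0.06 for RPG1 (anther), 0.03 for IRX10 (vascular), -0.88 for the clock gene GI and -0.80 and 0.23 for the auxin-conjugating GH3.5 and GH3.3. They were -1.13 and -0.46 for the stress regulators ZAT10 and WRKY53, -1.78 for AKINBETA1 (dark and sugar starvation), and -0.31 and 0.04 for the reference genes TIP41L and SAND. Adjusted over the list alone, GI, GH3.5, AKINBETA1 and MCM7 each gave 1 between DEX and MOCK, HSP23.5 gave 1 in DEX at 4 h against 0 h, and GI, GH3.5, AKINBETA1, LHCB4.3 and HSP23.5 each gave 1 in MOCK against 0 h. GI and AKINBETA1 were the only tested members of their lists, so for them this is the unadjusted p. Between DEX and MOCK it was 0.0275 and 0.0058 by limma, against 0.446 and 0.343 adjusted over all genes. The PRE/BANQUO, pollen, seed, meristem and jasmonate lists had 0 tested members.

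Plastid-encoded transcripts, a list added after seeing the data, had 69 probe sets. In MOCK they were lower than at 0 h in 66 of 69, with a median log2 difference of -0.32 (camera adjusted p = 5.8e-05). They were higher in 68 of 69 after DEX than after MOCK at 4 h (median 0.25, adjusted p = 4.6e-05), and between DEX at 4 h and 0 h the median was -0.03. Singly, 0 of the 69 passed the threshold over all genes in these comparisons. The medians per array, relative to the 0 h mean, overlapped, at -0.53, -0.38 and 0.07 in MOCK and -0.25, -0.12 and 0.30 at 0 h. With an estimated correlation the adjusted p was 0.370 and 0.430 for the MOCK comparisons. Without DEX 0 h replicate 3 the difference between MOCK and 0 h had a median of -0.17 and an adjusted p of 0.0772, and without DEX 4 h replicate 3 that between DEX and MOCK had 0.10 and 0.0656 and that between DEX at 4 h and 0 h passed (median -0.17, adjusted p = 0.0207). The median between DEX and MOCK was also 0.13 without MOCK replicate 1, 0.43 without DEX 4 h replicate 1 and 0.41 without MOCK replicate 3, with an adjusted p under 0.05 each. Within technical batches the medians were -0.20, -0.33 and -0.22 for MOCK against 0 h and 0.17, 0.47 and 0.23 for DEX against MOCK. The signal of 25S ribosomal RNA was 2027 ± 1028 (SD, n = 3) in MOCK and 1073 ± 757 at 0 h, with a two-sided exact permutation p of 0.2, where the smallest possible p is 0.1.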

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

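The tests of explanations in this part were chosen after the results were seen. The level at 4 h differed between DEX and MOCK for the gibberellin list (camera adjusted p = 0.02317), the phenylpropanoid and flavonoid list (0.03023) and the plastid-encoded transcripts (4.608e-05). None of these held with an estimated correlation. The series has no MOCK arrays at 0 h, so a difference in the change over time cannot be told from one already present at 0 h.

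MOCK replicate 2 stood apart from the other 2 MOCK arrays. With it and 1 DEX array held out, probe sets that part the remaining 4 arrays by at least 2-fold placed it nearer the DEX mean in 86.7% (339 of 391), 63.8% (351 of 550) and 81.3% (265 of 326), whereas MOCK replicates 1 and 3 lay nearer the DEX mean in at most 13.5%; DEX replicate 2, in turn, lay nearer the MOCK mean in 71.8% and 73.2% when held out with MOCK replicates 1 and 3. The prediction for a swap was not met, since the DEX array held out with MOCK replicate 2 lay nearer the MOCK mean in at most 35.1%. Exchanging it with DEX replicate 1, however, parts 62 probe sets by 2-fold against 16 as labelled, and with DEX replicates 2 and 3 parts 8 and 4. The exchange with DEX replicate 1 also gave 23 limma calls against 0, though 1094 against 1558 at an unadjusted p under 0.05. A swap therefore stays open. Degraded RNA on MOCK replicate 2 is argued against by its actin 5' to 3' ratio of 0.655, above both other MOCK arrays and both other arrays of its technical batch. A single sample that received DEX in place of MOCK may account for part of it, because the lowest of the 3 shares, 63.8%, is above 50%, but of the probe sets called between MOCK and 0 h without it, it lay nearer the DEX 4 h mean in 135 of 151 that rose and only 86 of 138 that fell (median -0.71, against -0.52 to 0.02 on the DEX 4 h arrays and -1.40 and -1.43 on the other MOCK arrays), and JMT (43.5) and 4CL8 (111) read below both other MOCK arrays, though these 2 were chosen with it counted as MOCK. A mixed sample and a biological difference between plants were not tested, and the array was kept under its label.

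MOCK at 4 h lay further from 0 h than DEX at 4 h did, with 58 against 1 called probe sets, though without DEX 0 h replicate 2 or 3 or MOCK replicate 1 or 3 it was 0 against 0. Array scaling as the whole cause is argued against because 42 of the 58 calls were shared with quantile normalization, though median centring called 31. A difference in RNA integrity stays open: of 9 ratios (actin, GAPDH and ubiquitin 5' to 3' in 3 technical batches) 6 were lowest on the MOCK array. MOCK replicates 1 and 3 held all 6. The prediction took 3 as the number expected by chance. The batches were read partly from these same ratios, and the ratios of 1 array are not independent, so that number is not a fair measure here. The pairing of DEX 0 h with DEX 4 h arrays, which the fit of all 9 arrays does not use, cannot be told apart as a cause: with a replicate block and only 2 groups in the fit, the counts at an unadjusted p under 0.05 were 2179 for DEX and 2087 for MOCK, but 6 and 330 passed the threshold. The MOCK solvent, handling and time of day were not tested and stay open, as does an effect of DEX that offsets the change over time.

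Plastid-encoded transcripts were lower in MOCK (median log2 -0.32 against 0 h). A smaller carry-over of RNA without poly(A) tails into the MOCK labelling cannot be told apart: 25S ribosomal RNA was higher in MOCK than at 0 h in every technical batch, by at least 1.33 times, but the signals of the groups overlapped (two-sided exact permutation p = 0.2, smallest possible 0.1). A smaller share of green tissue cannot be told apart, since the light harvesting and Rubisco list had a median of -0.59 over 4 members, 3 of them lower, but an adjusted p of 0.0721. A biological effect of DEX on plastid transcripts was not tested separately.

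With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For DEX against MOCK at 4 h the real split gave 0 calls and the highest other 23, so all 10 gave as many, and at an unadjusted p under 0.05 it gave 1558 against 2255, with 2 splits as large. The split with 23 sets DEX replicate 1 with MOCK replicates 1 and 3, which is the exchange of MOCK replicate 2 with DEX replicate 1. The split with 2255 exchanges MOCK replicate 2 with DEX replicate 2 and gave 0 calls. How many calls such splits give in samples without further structure was not computed. The 23, and the 14 for DEX at 4 h against 0 h, therefore do not show a structure beyond the labels. For DEX at 4 h against 0 h the values were 1 and 14 (2 splits as large) and, unadjusted, 747 and 1437 (6 splits); the 3 other splits that part all 3 replicate pairs gave 0 calls and 46, 105 and 193 unadjusted, whereas those above the real split part 1 pair. For MOCK against 0 h they were 58 and 0 (1 split) and, unadjusted, 2064 and 1993 (1 split).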

How the results depend on the processing

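The technical block and the fit of 2 groups with a replicate block were chosen after seeing the data; the cause of the changes was not tested except where noted. Calls for DEX against MOCK at 4 h (0) became 35 with array weights, 1 with only the 2 groups in the fit, 19 with the technical block, 84 by the fold rule, and 0 to 371 with 1 array left out. Calls for DEX at 4 h against 0 h (1) became 0 with an offset of 64, without the intensity trend, with robust eBayes, with only the 2 groups, with the replicate block, with the technical block and at an adjusted p of 0.01, 6 with 2 groups and a replicate block, 53 by the fold rule, and 0 to 76 with 1 array left out. Calls for MOCK at 4 h against 0 h (58) became 38 with an offset of 64, 3 with no dim filter, 31 with median centring, 3 without the trend, 587 with array weights, 230 with only the 2 groups, 185 with the replicate block, 396 with the technical block, 330 with 2 groups and a replicate block, 293 and 0 at adjusted p of 0.1 and 0.01, 362 by the fold rule, and 0 to 289 with 1 array left out. Median centring called 19 higher and 12 lower, against 21 and 37. Genes changed only after DEX (0) became 2 by the fold rule. Lists passing between DEX and MOCK (2) became 0 with the dimmest 50% left out, where fewer members are tested, 0 with an estimated correlation, 0 with fry and 0 to 3 with 1 array left out. Lists in DEX at 4 h against 0 h (0) became 1 with no dim filter and 0 to 1 with 1 array left out. Lists in MOCK against 0 h (3) became 1 with the dimmest 50% left out, 0 with an estimated correlation, 0 with fry and 0 to 4 with 1 array left out. The replicate numbers did not pair MOCK with the DEX groups: deviations of equal-numbered arrays correlated at -0.13, -0.02 and 0.28 with DEX 0 h and at -0.04, -0.06 and 0.26 with DEX 4 h. The replicate block changed 0 list calls. Named genes kept their direction in 620 of 622 values under other settings and 438 of 441 with 1 array left out, and 196 of these lost and 42 gained the threshold. Except for RBE, the naming rule took only genes whose groups do not overlap. Most directions were therefore fixed by that choice, and their agreement is no measure of stability. List values stayed on their side of the threshold in 522 of 558, 28 lost and 8 gained it, and 0 calls reversed. Most of the 558 belong to lists that did not pass with all arrays, so the 522 does not measure how stable the passing lists are. Probe sets with a mean over all arrays at or under a signal of about 51.4 were not tested.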

Other observations

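HSP23.5, AT2G04050, UGT73C1 and SBT3.5 had higher mean signals at 4 h in both treatments than at 0 h. None passed the threshold in DEX at 4 h against 0 h; the 4 were picked after their values were seen and were not tested as a group. HSP23.5, a mitochondrial small heat shock protein, was at 83.9 ± 42.4 (SD, n = 3) at 0 h, 1889 ± 1511 after DEX and 1357 ± 1419.5 after MOCK (log2 3.86 for DEX at 4 h against 0 h, SE 0.809, adjusted p = 0.476 by limma). The MATE efflux carrier gene AT2G04050 was at 16.6 ± 12.8, 648 ± 625 and 440 ± 257, and the glucosyltransferase gene UGT73C1 at 69.1 ± 15.8, 441 ± 284 and 240 ± 96.4. The subtilase gene SBT3.5 was at 87.6 ± 29.4, 1150 ± 824 and 779 ± 454. HSP23.5 read 378, 1888 and 3400 on DEX replicates 1, 2 and 3 at 4 h, and 548, 2996 and 527 on the MOCK replicates. On DEX replicate 1 at 4 h AT2G04050 read 65.1 and UGT73C1 139, below the median signal of any array, as did UGT73C1 on MOCK replicate 1 (164).

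DEX replicate 1 at 4 h and DEX replicate 1 at 0 h were the pair with the highest correlation across genes (r = 0.977, over genes, which are not independent replicates). MYC4, a transcription factor of the jasmonate pathway, was at 339 ± 77.7 at 0 h, 217 ± 40.9 after DEX and 135 ± 24.98 after MOCK, with a log2 difference between MOCK and 0 h of -1.22 (SE 0.239, adjusted p = 0.0675 by limma).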
